A study of Mus musculus with 6 samples.

How the data were processed

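RNA of mouse bone marrow was measured on 6 arrays, 3 labelled wild type and 3 labelled diabetic, and the groups were taken from the sample labels. Per the labels' protocols, marrow was flushed from femurs and tibiae, RNA was extracted with Trizol and a column kit, and whole-transcript cDNA was amplified, fragmented and biotinylated for Affymetrix arrays. The dye field of the labels names Cy3 in place of biotin, a difference the sources used here do not settle. The deposited values were log2 signals per probe set, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, makes the distributions of the arrays equal and summarises the probes of a set, so that a shift shared by most genes of an array cannot be seen. The software version and the genome build are not given in the sources used here. Scanner images and probe intensities were not analysed here.

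The table held 35556 probe sets. Of these, 21789 had 1 gene symbol in the platform annotation used, 1621 had several and 12146 had none there. Of the single symbols, 21698 matched the RefSeq gene table of GRCm38.p6 and 0 changed name. That table served only for names, chromosomes and gene order, and no coordinates are printed. No gene was named from a probe set with several symbols. The 19938 genes left were reduced to those with a mean log2 signal over the 6 arrays at or above 7.50, the 40th percentile of named probe sets, which gave 12029 genes. For the 999 genes with more than 1 probe set, the set with the highest mean stood for the gene.

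Diabetic and wild type arrays were compared gene by gene with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariate, and with the data.table package, version 1.17.8. Adjusted p values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and values adjusted over a list alone or over another set of probe sets are named so. Lepr lay below the level filter and was fitted with all 21789 probe sets that had 1 symbol. The direction is diabetic minus wild type throughout. Errors of log2 changes are the standard errors of the limma fit, errors of list shifts are standard errors over array means, and errors of levels are standard deviations over 3 arrays. Lists of 5 or more tested members were compared with limma's camera with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Of 36 lists fixed before the data were examined, 34 were tested, 1 had too few members (cartilage, 3 tested members, mean change -0.01) and 1, the sex-linked genes, was only listed. Shares of changed genes around Lepr were compared with Fisher's exact test, two-sided, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

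Genes were named by a rule also fixed before the data were examined. It took the leptin receptor genes and 1 further item that is not reported here, and up to 12 genes per direction with the largest change among those past the threshold with separate groups. It also took up to 4 members of each list that passed and of 5 control lists. Unnamed gene models were left out of the naming, which removed 1 higher and 1 lower gene past the threshold. Other genes, such as further members that passed over a list alone and members at the ends of a list's range, were named after their values were seen.

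The gene and list tests were tested on simulated data for the comparison of diabetic with wild type marrow, with 200 changed genes among 12029. The share recovered was 98% at a log2 change of -1.5, 98% at -1, 64% at -0.5 and 62% at 0.5, and 14 unchanged genes were called. A simulated list was found, and 0 of 34 other lists were called. The simulated noise was drawn for each gene alone, so this count does not show how the list test behaves when genes vary together. In the real data the estimated correlation was 0.38 for the interferon response list and 0.86 for the B cell precursor list.

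Alternatives were no level filter, a filter at the 60th percentile, a further quantile normalization, median centring, the mean of a gene's probe sets, eBayes with trend and robust settings, array weights, a replicate block, other thresholds, all probe sets, and leaving out each array in turn. Added after seeing the data were the removal of X and Y genes, the removal of interferon response genes from the other lists, and further settings for the chromosome 4 comparison and for the similarity of the arrays. Probe sets with several symbols or none, 13767 in number, were tested apart from the genes, and 0 of them passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, while 773 had an unadjusted p under 0.05.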

Results

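The series measured RNA from mouse bone marrow on 6 single-colour Affymetrix gene arrays, 3 from wild type animals and 3 from diabetic animals. The labels give the strain background as BKS with the db variant of the leptin receptor gene Lepr, a standard mouse model of obesity and type 2 diabetes, and give every animal as a male of 10 weeks. The marrow had been washed out of the shafts of the femurs and tibiae with no further treatment and no sorting step in the labels, so each array read a mixture of blood-forming, immune and stromal cells. Values were log2 signals after robust multi-array averaging (RMA). The median log2 signal of the 6 arrays lay between 7.67 and 7.73, and the number of arrays, 3 per group, limits the precision. Whether each array held 1 animal or a pool is not given in the sources used here, so the p-values measure the spread between these samples.

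The main question was which transcripts differed between diabetic and wild type marrow. Genes of the interferon response, the antiviral program that type I interferons switch on, made up most of the largest falls. Ifit3, an antiviral RNA-binding protein, fell by 1.78 ± 0.16 on the log2 scale (SE, n = 3 per group), which was 3.43-fold lower in diabetic marrow. Rtp4 was 3.19-fold lower, Ifi27l2a 3.07-fold lower and Oas2, a sensor of double-stranded RNA, 2.81-fold lower. The gene with the smallest adjusted p was Ifi205 (probe set 10360406), a member of the Ifi200 family of nucleic acid sensors, whose log2 signal was 8.74 ± 0.02 in wild type and 7.21 ± 0.15 in diabetic marrow (SD, n = 3 each), with an adjusted p of 0.00124 in limma with Benjamini-Hochberg adjustment. In the other direction, Vcan, the matrix proteoglycan versican, rose by 1.43 ± 0.22 on the log2 scale (SE, n = 3 per group), which was 2.70-fold higher.

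In all, 52 of 12029 genes tested passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 12 higher and 40 lower in diabetic marrow. At an unadjusted p under 0.05 there were 864 genes, 479 higher and 385 lower, against 601.45 expected by chance. For each of the 52 genes the 3 diabetic values all lay on one side of the 3 wild type values. Selection by a small p largely ensures this, so it adds no support. Such a separation was seen for 12.4% of all genes tested, where chance gives 10%. Leaving out 1 array moved the count to 58, 13 and 70 without wild type replicate 1, 2 or 3. Without diabetic replicate 1, 2 or 3 it was 5, 3 and 12. When all 35556 probe sets were tested with no filter on level, 1 passed, that of Ifi205.

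**Figure D1:**
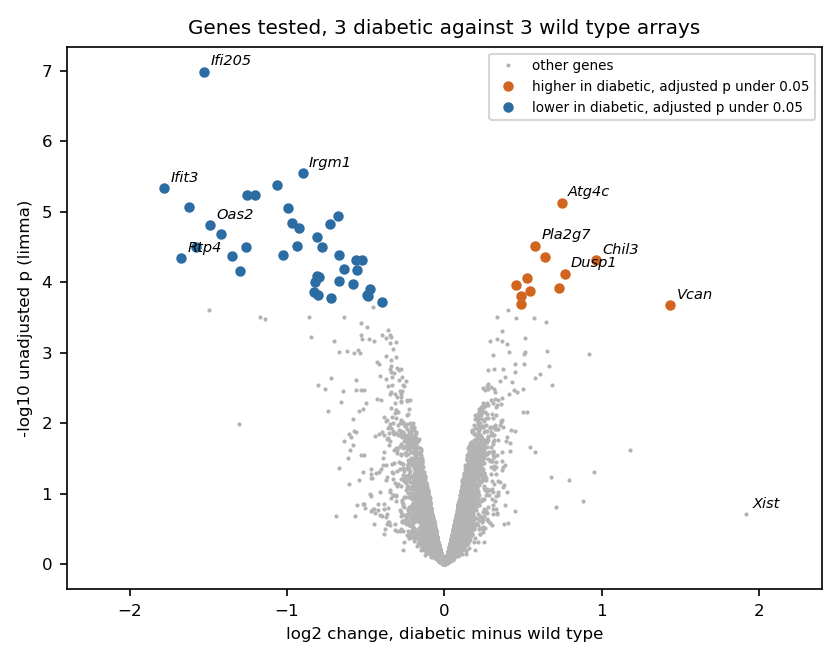
Each point is 1 of the 12029 genes tested, with the log2 change (diabetic minus wild type) on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis. The 40 genes past the adjusted threshold on the left outnumber the 12 on the right, and Ifi205 has the smallest p.

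The 12 named genes with the largest falls were Ifit3, Rtp4, Ifi27l2a, Ifi213, Ifi205, Oas2, Usp18, Oasl2, Irf7, Xaf1, Slfn5 and Ifi207. Usp18, a protease that removes the ubiquitin-like modifier ISG15, fell by 1.42 ± 0.16 on the log2 scale (SE, n = 3 per group). Irf7, a transcription factor that drives type I interferon genes, fell by 1.30 ± 0.17. Slfn5 fell by 1.25 ± 0.12, Ifi207 by 1.20 ± 0.11, Ifi213 by 1.58 ± 0.18, Xaf1 by 1.26 ± 0.15 and Oasl2 by 1.35 ± 0.16. Their adjusted p values in limma with Benjamini-Hochberg adjustment ranged from 0.00124 for Ifi205 to 0.0260 for Irf7. The Ifi200, oligoadenylate synthetase and Schlafen families hold close paralogs, so the signal of a member may include RNA of its relatives.

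The list of interferon response genes, fixed before the data were examined, had 22 tested members, and all 22 were lower in diabetic marrow. Of these, 14 passed the threshold over all genes and 22 when adjusted over the list alone. The 14 became 17, 6 and 15 without wild type replicate 1, 2 or 3 and 3, 0 and 3 without diabetic replicate 1, 2 or 3. The mean log2 signal of the list was 9.74 ± 0.20 in wild type and 8.72 ± 0.07 in diabetic marrow (SD, n = 3 each), a shift of -1.02 ± 0.12 (SE). Its adjusted p was 7.16e-52 in limma's camera test with a preset correlation and Benjamini-Hochberg adjustment, and the adjusted p was 0.148 with an estimated correlation. In limma's fry test, which asks whether the genes of a list move one way on balance, the adjusted p after Benjamini-Hochberg was 0.0259. Ifit1, which missed the threshold over all genes, had a log2 change of -1.49 ± 0.24 and an adjusted p of 0.0537 in limma with Benjamini-Hochberg adjustment. The smallest differences of the list were those of Bst2, at -0.27 ± 0.06, and Ifit2, at -0.30 ± 0.09.

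**Figure D2:**
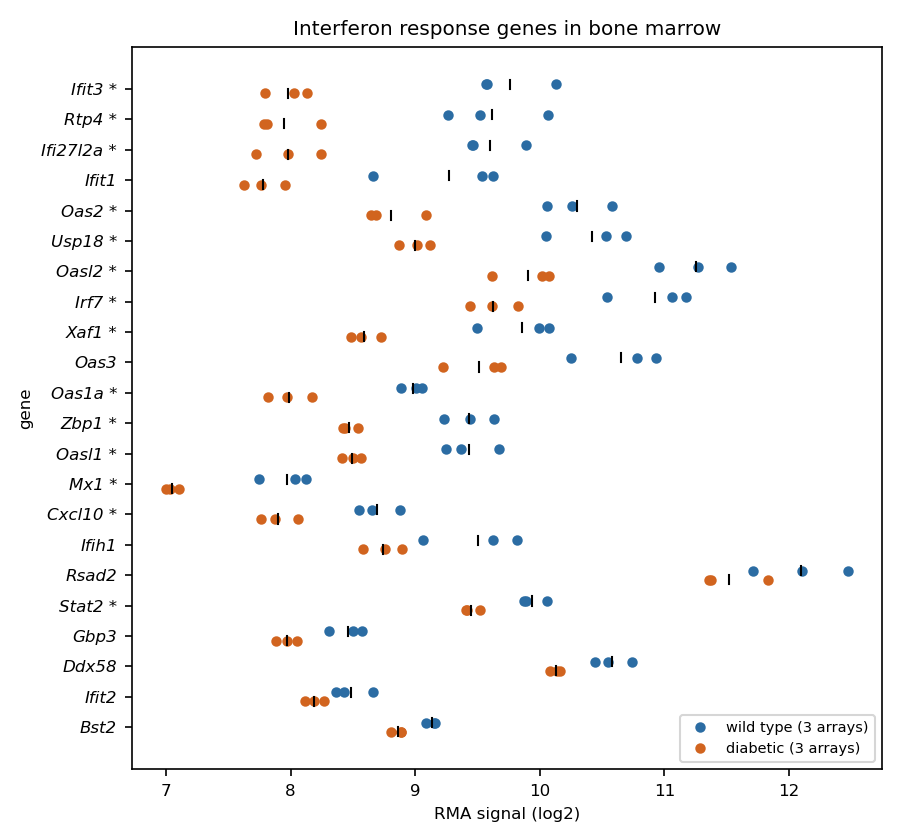
RMA log2 signal (horizontal axis) of the 22 tested interferon response genes (vertical axis) in 3 wild type and 3 diabetic arrays, with 1 point per array, a vertical tick for each group mean and a star for the 14 genes past the adjusted threshold. The diabetic mean lies below the wild type mean for all 22 genes.

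Of the 40 lower genes, 14 were in that list and 26 were outside it. The list is a fixed selection, so a gene outside it, such as Ifi205, may still belong to the interferon response. The 26 included Cxcl9, a T cell chemokine, at -1.06 ± 0.09, Irgm1, an immunity-related GTPase, at -0.90 ± 0.08, Parp12 at -1.02 ± 0.12 and Dhx58 at -0.81 ± 0.09. They also included Fcgr1, a high-affinity receptor for immunoglobulin G, at -0.68 ± 0.07, and Mertk, a receptor used in the clearance of dead cells, at -0.47 ± 0.07. These 6 genes lie outside the naming rule and were chosen after their values were seen.

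Among the 12 genes that rose past the adjusted threshold, Chil3, a chitinase-like protein of neutrophils and macrophages, rose by 0.96 ± 0.12 on the log2 scale (SE, n = 3 per group), or 1.95-fold. It has close paralogs that can share signal. Dusp1, a phosphatase that switches off MAP kinases, was 1.70-fold higher, and Atg4c, a protease of autophagy, was 1.68-fold higher. Pla2g7, the plasma platelet-activating factor acetylhydrolase, was 1.49-fold higher, Itga8, an integrin subunit, 1.56-fold higher, and Hgf, hepatocyte growth factor, 1.37-fold higher. Tmem71, Mkx and Tspan15 rose by 0.52 ± 0.07, 0.49 ± 0.07 and 0.49 ± 0.07. Dpep2 rose by 0.73 ± 0.10, but its second probe set, which was dimmer, gave 0.17 ± 0.13, so its probe sets disagreed. The adjusted p values of these 11 named genes ran from 0.0116 for Atg4c to 0.0483 for Vcan in limma with Benjamini-Hochberg adjustment. The call on Vcan was lost in 8 of 14 alternatives. Among these were the level filter at the 60th percentile, median centring and a further quantile normalization. The adjusted p of Vcan in limma with Benjamini-Hochberg adjustment ran from 0.000107 to 0.268 over all alternatives. Itga8, Atg4c, Dpep2 and Mkx had low wild type means, 7.19, 7.30, 7.43 and 7.498, under the filter's cut of 7.5025. They passed the level filter only through their diabetic values. Among the lower genes, Ifi205, Ifi213, Fcgr1 and Mx1 had diabetic means under that cut, at 7.21, 7.48, 7.46 and 7.05.

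Marker and pathway lists were then compared to describe which cell types and programs moved. Of 34 lists tested, 10 passed an adjusted p of 0.05 in limma's camera test with Benjamini-Hochberg adjustment, 3 higher and 7 lower. None of the 10 passed with an estimated correlation, where the smallest adjusted p was 0.148, and 2 passed in fry, the interferon response and plasma cell lists.

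Plasma cell genes, of the cells that secrete antibody, had 8 tested members, all lower in diabetic marrow, and the mean of the list shifted by -0.38 ± 0.08 (SE, n = 3 per group). The adjusted p was 4.08e-05 in limma's camera test with Benjamini-Hochberg adjustment and the adjusted p was 0.148 with an estimated correlation. No member passed over all genes and 3 passed when adjusted over the list alone, Igha at -0.85 ± 0.15, Derl3 at -0.35 ± 0.11 and Sdc1 at -0.23 ± 0.08. Irf4, a transcription factor needed for plasma cells, had -0.51 ± 0.31 and did not pass, with -0.89 to -0.29 when 1 array was left out.

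The dendritic cell list, with 14 tested members, 11 of them lower, shifted by -0.19 ± 0.09 (SE, n = 3 per group), and its adjusted p was 0.466 with an estimated correlation. Adjusted over the list alone, 5 members passed, Itgax, Cox6a2, Bst2 and Tcf4 lower and Flt3 higher, and 0 passed over all genes. Itgax, which encodes the CD11c integrin, was at -0.37 ± 0.07, and Flt3, a cytokine receptor also found on early progenitors, was at 0.23 ± 0.06. Bst2 is also a member of the interferon response list.

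The monocyte and macrophage list, with 20 tested members, 13 of them lower, shifted by -0.11 ± 0.03 (SE, n = 3 per group), with an adjusted p of 0.385 with an estimated correlation. Adjusted over the list alone, 9 members passed, and 0 did over all genes. Axl, C1qb, Siglec1, Mrc1, Cd68, Hmox1, C1qa and C1qc were lower and Cd163, a scavenger receptor for haemoglobin, was higher. C1qb, a chain of complement C1q that resident macrophages make, was at -0.62 ± 0.12, Axl at -0.53 ± 0.09, Siglec1 at -0.34 ± 0.07 and Cd163 at 0.34 ± 0.06.

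Genes of B cell precursors were lower as a list, with a mean shift of -0.27 ± 0.31 (SE, n = 3 per group) that was smaller than its own error. The list mean was 10.89, 10.65 and 9.92 on the wild type arrays and 10.27, 10.37 and 10.00 on the diabetic arrays. Of 20 members, 19 were lower and 0 passed over all genes or over the list alone, and the adjusted p was 0.650 with an estimated correlation. Rag1, which cuts DNA for receptor gene assembly, was at -0.60 ± 0.21, Dntt at -0.47 ± 0.25, Blnk at -0.47 ± 0.26 and Vpreb3 at -0.50 ± 0.32. When 1 array was left out these ran from -0.89 to -0.44, -0.71 to -0.15, -0.77 to -0.24 and -0.86 to -0.25. The shift was -0.07 without wild type replicate 1, -0.56 without wild type replicate 3 and -0.16 without diabetic replicate 3, and the camera call was lost in the first and the last of these.

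Cholesterol synthesis genes were lower in 17 of 18 tested members, with a mean shift of -0.22 ± 0.16 (SE, n = 3 per group), and none passed over all genes or over the list alone. Idi1 was at -0.61 ± 0.23, Hsd17b7 at -0.38 ± 0.14, Fdps at -0.37 ± 0.15 and Srebf2, the transcription factor of the pathway, at -0.36 ± 0.12. When 1 array was left out these ran from -0.80 to -0.34, -0.49 to -0.22, -0.49 to -0.21 and -0.45 to -0.22. Wild type replicate 3 had a list mean of 9.21, while the other 5 arrays lay between 8.60 and 8.77, and without it the shift was -0.06 and the camera call was lost. The adjusted p was 0.482 with an estimated correlation. The unfolded protein response list, with 17 of 23 members lower and 0 past either adjustment, shifted by -0.05 ± 0.04, with Calr, Creld2, Pdia4 and Pdia6, the members with the smallest p, at -0.20, -0.25, -0.20 and -0.18, where Pdia4 was at -0.11 with the mean of its probe sets. Its adjusted p was also 0.482 with an estimated correlation. The shift was -0.08 without wild type replicate 1, -0.03 without wild type replicate 3 and -0.08 without diabetic replicate 1.

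The 3 lists that were higher included the glucocorticoid response, with 13 of 18 members higher and a mean shift of 0.16 ± 0.05 (SE, n = 3 per group). Its adjusted p was 0.385 with an estimated correlation. Dusp1 passed over all genes, and Dusp1, Per1, Ddit4 and Tsc22d3 passed when adjusted over the list alone, the last 3 with log2 changes of 0.40 ± 0.07, 0.58 ± 0.13 and 0.46 ± 0.11, and with array weights Per1 was at 0.25. Per1 belongs also to the circadian clock list, which did not pass. The immediate early and heat shock list, kept as a sign of handling stress, shifted by 0.14 ± 0.10, with Dusp1 and Ier2 (0.41 ± 0.08) past over the list alone. Ier3 was at 0.45 ± 0.14, with 0.28 to 0.54 when 1 array was left out, and Junb at 0.26 ± 0.08. Of its 25 members 18 were higher, and the adjusted p of the list was 0.482 with an estimated correlation. Its shift was 0.12 without wild type replicate 3 and 0.07 without diabetic replicate 1, where the camera call was lost, and 0.23 without diabetic replicate 3. Late neutrophil genes shifted by 0.13 ± 0.08, but their median change was only 0.05, with 12 of 18 members higher, and the adjusted p was 0.670 with an estimated correlation. Chil3 passed both adjustments, and Il1b, Cd177 and Retnlg were at 0.58 ± 0.21, 0.16 ± 0.10 and 0.14 ± 0.08, with 0.35 to 0.71, 0.08 to 0.27 and 0.08 to 0.18 when 1 array was left out. The camera call was lost without wild type replicate 3, diabetic replicate 1 or diabetic replicate 3, where the shift was 0.10, 0.09 and 0.09, and the shift was 0.21 without diabetic replicate 2.

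**Figure D3:**
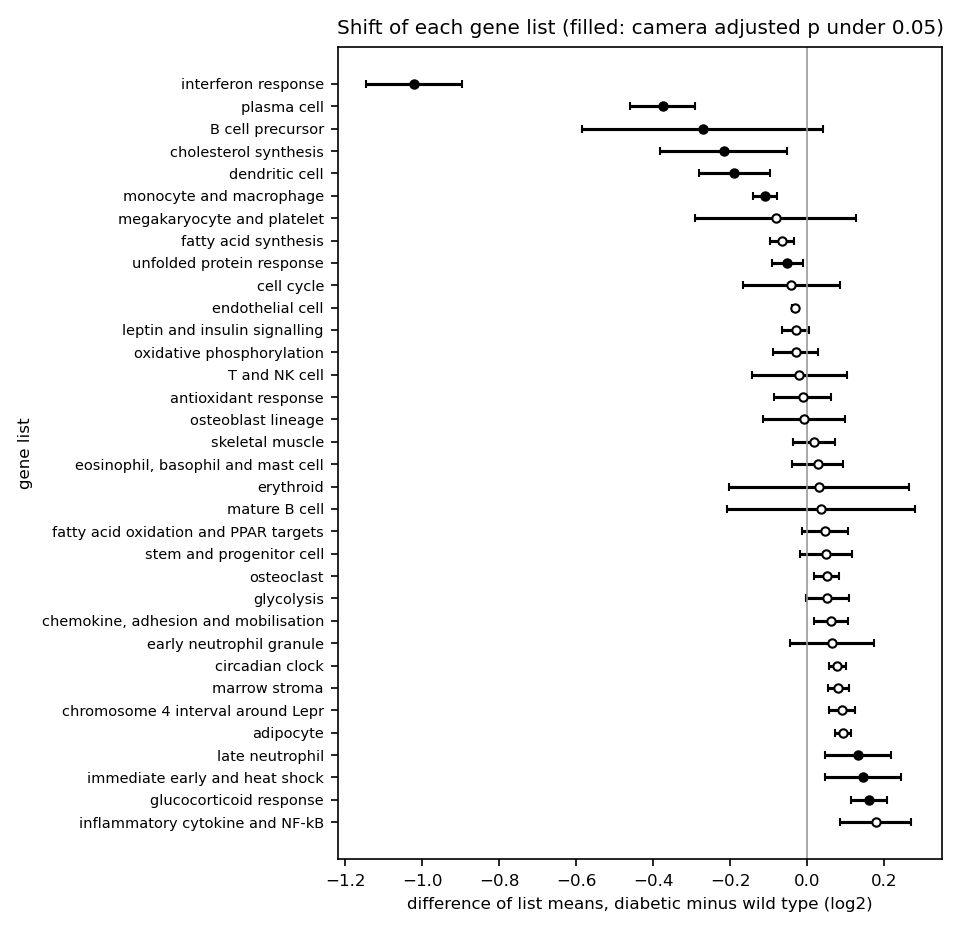
Difference of each list's mean log2 signal, diabetic minus wild type (horizontal axis), for the 34 lists tested (vertical axis), with bars of 1 standard error over 3 arrays per group and filled points for the 10 lists past an adjusted camera p of 0.05. The interferon response list stands furthest from 0, at -1.02, followed by the plasma cell list at -0.38.

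The other 24 lists did not pass, with adjusted p from 0.0533 for the inflammatory cytokine and circadian clock lists to 0.947 for the antioxidant response in limma's camera test with Benjamini-Hochberg adjustment. The inflammatory cytokine list passed, in the upward direction, in 10 of 17 alternatives and the circadian clock list in 4 of 16, while neither did with an estimated correlation, where the adjusted p was 0.573 and 0.466. The erythroid, skeletal muscle and adipocyte lists, kept as controls, were among them. Late neutrophil and B cell precursor genes had been kept as controls too, but these lists passed, so not all controls stayed unchanged. Their adjusted p was 0.0296 and 0.000863 in limma's camera test with Benjamini-Hochberg adjustment. Erythroid genes shifted by 0.03 ± 0.23 and skeletal muscle genes by 0.02 ± 0.05 (SE, n = 3 per group). Adipocyte genes shifted by 0.09 ± 0.02, with Lpl at 0.31 ± 0.10, Fabp4 at 0.23 ± 0.14, Cebpa at 0.13 ± 0.07 and Plin4 at 0.10 ± 0.07. When 1 array was left out the last 3 ran from 0.12 to 0.37, 0.08 to 0.19 and 0.05 to 0.15, and Fabp4 was at 0.03 with array weights. Among erythroid genes Car1 was at 0.27 ± 0.08, Tfrc at 0.16 ± 0.16, Aqp1 at 0.12 ± 0.21 and Alas2 at 0.04 ± 0.08, with 0.02 to 0.29 for Tfrc when 1 array was left out. Among muscle genes Eno3 was at 0.11 ± 0.11, Mb at 0.06 ± 0.09, Tnnc2 at -0.03 ± 0.06 and Tnnt3 at 0.03 ± 0.08, and Eno3 ran from 0.02 to 0.20 when 1 array was left out and was at 0.30 with array weights. No member of the erythroid, skeletal muscle or adipocyte list passed over all genes or over its list alone. The osteoblast list had a mean change of -0.01 while its median was 0.06 and its test pointed up. The leptin and insulin signalling list had a median of 0.02 while its mean was -0.03 and its test pointed down.

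The genotype label led to a look at the leptin receptor itself. The Lepr probe set had a log2 signal of 5.80 ± 0.14 in wild type and 5.69 ± 0.04 in diabetic marrow (SD, n = 3 each), at the 10.2 percentile of the named probe sets and below the level filter. Its log2 change was -0.11 ± 0.08 (SE), with -0.16 to -0.03 when 1 array was left out. The adjusted p of Lepr was 0.983 in limma with Benjamini-Hochberg adjustment, in a separate fit of the 21789 probe sets with 1 symbol and no level filter. Leprot, which overlaps Lepr at its start, was at 0.09 ± 0.11 with an adjusted p of 0.973 in limma with Benjamini-Hochberg adjustment over the 12029 genes tested, and of 0.999 in the fit used for Lepr. The db change alters the splicing of the long receptor form, so a signal for the whole gene need not show it and does not check the labels.

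Around Lepr on chromosome 4 the 2 groups could carry different haplotypes, and a list of genes there was compared with the rest. Of its 22 tested genes, 1 passed the adjusted threshold, Atg4c, against 51 of 12007 elsewhere (odds ratio 11.2, two-sided Fisher's exact p = 0.0910). At an unadjusted p under 0.01 the counts were 1 of 22 and 241 of 12007, with an odds ratio of 2.32 (95% confidence interval 0.0560 to 14.6) and a two-sided Fisher's exact p = 0.361. This odds ratio ran from 2.14 to 3.94 when 1 array was left out, and the smallest p over all alternatives was 0.0686. Among genes within 10 Mb of Lepr on the GRCm38.p6 assembly, the odds ratio was 3.59 at the adjusted threshold (1 of 66 genes, two-sided Fisher's exact p = 0.249) and 0.748 at an unadjusted p under 0.01 (two-sided Fisher's exact p = 1). Atg4c had a log2 signal of 7.30 ± 0.08 in wild type and 8.04 ± 0.09 in diabetic marrow (SD, n = 3 each). Its nearest tested neighbours in gene order on the GRCm38.p6 assembly, Usp1 and Alg6, were at -0.10 ± 0.09 and -0.02 ± 0.07 (SE).

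The arrays were also compared as wholes. The mean correlation across the genes tested was 0.987 between wild type arrays, 0.992 between diabetic arrays and 0.987 between the groups. Genes are not independent replicates, and these values carry no test. The first principal component held 39.8% of the variance and set wild type replicate 1, at -12.1, against wild type replicate 3, at 16.5. The second, with 27.6%, separated the groups, with wild type arrays from 5.75 to 8.15 and diabetic arrays from -9.11 to -5.75.

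The sex label was compared with the genes that report sex. Xist, the RNA that silences one X chromosome in female cells, had a log2 signal of 7.04 on wild type replicate 1 and between 12.64 and 12.84 on the other 5 arrays. The Y-linked genes ran the other way, with Eif2s3y at 9.34, Kdm5d at 8.44 and Uty at 8.53 on wild type replicate 1. On the other 5 arrays Eif2s3y lay between 4.02 and 4.37, Kdm5d between 5.98 and 6.27 and Uty between 4.87 and 5.27. The wild type group was thus mixed for these genes and the diabetic group was not, and 5 arrays did not match the male label. Without wild type replicate 1, 58 genes passed the threshold, of which 40 were among the 52, and the interferon response list shifted by -1.13 ± 0.07 (SE). That array was singled out after its values were seen, although leaving out each array had been planned. With X and Y genes left out, an alternative chosen after seeing the data, 53 genes passed.

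**Figure D4:**
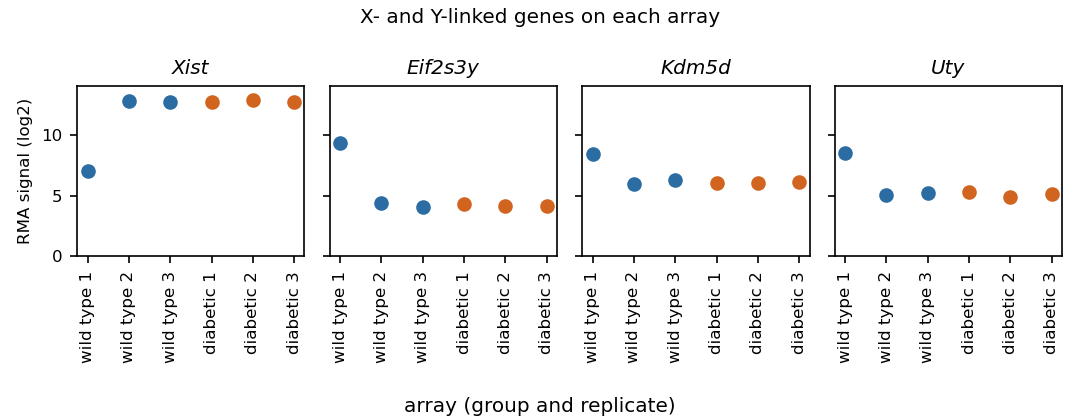
RMA log2 signal (vertical axis) of Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty on each of the 6 arrays (horizontal axis, group and replicate), with 1 point per array. Wild type replicate 1 is low for Xist and high for the Y-linked genes, and the other 5 arrays show the opposite.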

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

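The alternatives that removed X and Y genes, took interferon response genes out of other lists, or varied the chromosome 4 comparison and the array similarity beyond the planned settings were chosen after seeing the data. No called gene changed direction under any alternative, and neither did any called list. The count of genes changed in diabetic marrow, 52, lay between 35 and 59 under the filters, normalizations, probe set rule, variance model, fold thresholds and removal of X and Y genes. It was 1878 with array weights, whose estimation stopped before converging, and 1 with all probe sets, where the fit's prior spread was 0.107 against 0.0920 for the genes tested and 35556 features entered the adjustment. Leaving out 1 array gave 3 to 70 genes, with fewer samples in each fit, and of the 52 genes 40, 13 and 45 kept their call without wild type replicate 1, 2 or 3 and 5, 3 and 10 without diabetic replicate 1, 2 or 3. Deviations of same-numbered arrays from their group means had correlations of 0.327, -0.0428 and -0.0549, and not every array correlated best with its own number. With 3 arrays per group these values cannot decide whether the replicate numbers pair the samples. With a replicate block 2 genes passed, with fewer residual degrees of freedom.

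The 10 lists became 0 with an estimated correlation, where the adjusted p of the interferon response list was 0.148 (limma, Benjamini-Hochberg) and its shift of -1.02 is by construction untouched, and 2 in fry. Array weights ended the calls on the late neutrophil, cholesterol synthesis, unfolded protein response and glucocorticoid lists. Of the uncalled lists, 14 passed in the direction of the main test under 1 or more alternatives, 12 of them in at most 3. Lists that passed only in the other direction, such as mature B cell, are not in this count. Directions of tests turned only for results that had not been called, and the cause was not tested. These were skeletal muscle without a level filter (0.00323), mature B cell (0.0214), antioxidant (0.00356) and leptin and insulin (0.0308) with the 60th percentile filter, and antioxidant with renewed quantile normalization (-0.0161) and in fry (-0.0117). With array weights they were mature B cell (-0.16, now past the threshold), megakaryocyte (0.00541), antioxidant (-0.00874) and Tnnc2 (0.00653), and with the replicate block mature B cell (0.0356). Direction here is that of the list test, which can differ from the sign of the mean printed. The chromosome 4 odds ratio was 0 with the 60th percentile filter, which left Atg4c out.

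Leaving out 1 array turned further uncalled results. The ranges were -0.110 to 0.224 for erythroid, -0.205 to 0.181 for mature B cell, -0.109 to 0.0645 for T and NK cell, -0.235 to 0.0994 for megakaryocyte, -0.0331 to 0.0730 for eosinophil, -0.0581 to 0.0846 for osteoblast, -0.0122 to 0.0616 for skeletal muscle, 0.00443 to 0.0822 for fatty acid oxidation, -0.0677 to 0.0216 for oxidative phosphorylation, -0.115 to 0.0602 for cell cycle and -0.0694 to 0.0550 for antioxidant genes. For single genes they were -0.0130 to 0.199 for Leprot, -0.00900 to 0.144 for Mb, -0.0740 to 0.0139 for Tnnc2, -0.0234 to 0.105 for Tnnt3, -0.0738 to 0.306 for Aqp1 and -0.0317 to 0.0799 for Alas2. Mean correlations within wild type, within diabetic and between groups were 0.994, 0.996 and 0.994 without a filter and 0.977, 0.988 and 0.979 with the 60th percentile filter. Leaving out 1 array gave 0.979 to 0.993 within wild type and 0.989 to 0.994 within diabetic.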

Other observations

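The gene families below, and the tests of cell loss, of mixed RNA and of the interferon list on wild type replicate 1, were chosen only after the results were seen. The test on genes that escape X inactivation was set after the Xist and Y-linked pattern was known, but before the values of its genes were looked at. Most tested members of several related immune gene families had lower values in diabetic marrow. The families of this paragraph were picked because some members had been called. Those of the next paragraph, with 0 called members, were also picked after the values were seen, so none is independent evidence. All 7 tested members of the Ifi200 family were lower, with a median log2 change of -1.17, and 3 passed the adjusted threshold over all genes. All 4 guanylate-binding protein genes were lower, with a median of -0.46, and Gbp7 passed, while Gbp3 is also in the interferon response list. In the Schlafen family 7 of 8 members were lower, with a median of -0.30, and Slfn5 and Slfn8 passed. In the PARP family 8 of 11 were lower and 3 higher, with a median of -0.09, and Parp12, Parp9 and Parp14 passed. Paralogs within each family can share signal.

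All 10 tested immunoglobulin genes were lower, with a median of -0.48, and 0 passed over all genes. All 6 tested MHC class I genes were lower with a median of -0.28, and 0 passed. They were H2-T24, H2-Q4, H2-M3, H2-Q5, H2-T10 and H2-Q2, so the fall covers these members only, and 1 of them had separate groups. In MHC class II 6 of 8 were lower with a median of -0.03. Among genes of interferons and their receptors 2 were lower and 3 higher, and 0 passed. The members tested were Ifngr1, Ifngr2, Ifnar1, Ifnar2 and Ifna5, the only interferon gene among them.

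The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping gave 52 genes and the highest other gave 0, so 1 of the 10 groupings gave as many. At an unadjusted p under 0.05 the real grouping gave 864 genes, and 3 of the others gave more, with 965, 1067 and 1302, so that the excess over chance at that threshold is not particular to the real grouping. For lists, 7 of the 10 groupings gave at least the 10 lists of the real one, and the highest other gave 13.

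The interferon response list was lower in diabetic marrow by -1.02 on the log2 scale, and technical and cellular accounts of it were tested. The wild type array with the male pattern as the whole source is argued against, since the shift without it was -1.13 ± 0.07. Loss of a whole listed cell type rich in interferon response genes is argued against too, as far as its list mean follows cell number. This leaves out the B cell precursor list. Of 18 cell lists the plasma cell list fell furthest, by -0.38, and all 18 fell short of the interferon list by more than 2 standard errors. For B cell precursor genes that gap was 0.75 with a standard error of 0.37, too close to the bound to decide. Members of a list fell unevenly, from -0.85 for Igha to -0.06 for Xbp1 among plasma cell genes, so a mean may understate a loss. List means also do not test a loss of cells that make interferon. In the monocyte and macrophage list 13 members were lower and 7 higher, so its mean shift of -0.11 cannot show loss of a subset. A lower interferon signal in diabetic animals may account for the pattern, and so could a difference in infection or housing between the groups, which no value here tests.

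Xist was high and Y-linked genes low on 5 of the 6 arrays, all labelled male. RNA of female animals on those 5 arrays would also raise genes that escape X inactivation. The mean of Kdm6a, Kdm5c, Eif2s3x and Ddx3x differed by -0.44 on wild type replicate 1 from the mean of the other 5 (SD 0.05 between the 5), which goes with that account. Each gene was lowest on that array. The gap was widest for Kdm6a, at 9.94 against 10.64 to 10.86, and narrow for Ddx3x, at 10.98 against 11.01 and 11.06 on wild type replicates 2 and 3. A large share of male RNA on them is argued against by Eif2s3y, at most 3.18% of its signal on wild type replicate 1, while Kdm5d and Uty, at up to 22.2% and 10.4%, bound it less closely. Diabetic RNA on wild type replicate 1 was not decided by the test set in advance. Only 40 of 50 genes placed that array nearer the other wild type arrays, short of the 45 required. Its interferon response list mean of 9.52, a measure chosen after the results were seen, lay 0.74 above the highest diabetic array. That goes against diabetic RNA only if the list follows genotype and not infection or housing. A wrong sex label on the 5 arrays and samples swapped with others outside the series cannot be separated with these values.

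Atg4c rose near Lepr on chromosome 4 while its neighbours Usp1 and Alg6 did not pass. A haplotype that differs between the groups around Lepr may change its level or the binding of its probes. The interval list had an odds ratio of 2.32 at an unadjusted p under 0.01 (two-sided Fisher's exact p = 0.361), and 2.14 to 3.94 when 1 array was left out, and with 1 changed gene among 22 the counts are too few to decide. In the window of 10 Mb either side of Lepr the odds ratio was 0.748 with 1 of 66 genes. An effect of diabetes on Atg4c stays open as well.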
